A study of Phyllostachys edulis with 18 samples.

How the data were processed

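Gene expression was measured by RNA sequencing in roots and shoots of moso bamboo seedlings, with 3 libraries for each of 6 groups: mock, propiconazole (PPZ) and propiconazole followed by brassinolide (BL) in each tissue. Groups were taken from the sample labels. The deposited files are 4 tables of 31787 genes, 1 for each pair of groups that the authors compared within a tissue, and each gene carries protein and nucleotide database matches. Expression values are RPKM (reads per kilobase of gene, scaled to library size), per the file headers. The authors also deposited for each gene a fold change, which equals the ratio of the mean RPKM of the groups in every gene with a finite fold within 0.1%, and its log2; where the fold is 0 that column holds 0 (375, 215, 586 and 225 genes in the root BL, shoot BL, root PPZ and shoot PPZ tables). A p-value and a false discovery rate complete each table, deposited by the authors and from edgeR per the labels. Aligner, read counter, genome build and annotation version are not given in the sources used here. A few items of the tables are not reported here.

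The columns headed PPZ in both BL tables hold the mock values. In 31787 of 31787 genes (100%) each of these 6 columns equals the mock column of the same number in the PPZ table of its tissue, where between 10.5% and 13.6% of genes equal the column headed PPZ. The 6 columns were not used. PPZ values were taken from the PPZ tables and BL values from the BL tables, so that all 18 libraries entered once, and the authors' folds and false discovery rates in the BL tables were read as describing BL against mock. Whether the headings or the values are in error is not stated in the labels.

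Read depth was recovered from the RPKM values, because a gene with few reads takes whole multiples of a fixed step in each library. All 29254 genes with a value above 0 were whole reads in every library, within 0.002 read or, where larger, 3e-07 of the read number. Reads behind the RPKM of a library, in units of 1e6, numbered 15.5 to 25.9, with 57.3% to 60.6% of these in the listed genes. The median recovered gene length was 1086 bp and 93.7% of the lengths were multiples of 3, so these are coding lengths. In a gene of 1000 bp, 1 read gives between 0.039 and 0.065 RPKM, depending on the library. This step was tested on simulated reads for 31787 genes, where the largest error of a library total was 0.03% and 98.8% of genes had every read number recovered; a smaller simulated set of genes did not recover the totals. Between replicates the chi-square per gene, for genes with at least 20 reads, was 6.69 to 34.2 over 18 pairs, well above counting error alone, so depth is not what limits the precision of abundant genes.

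The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1), for genes with at least 1 RPKM in 3 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A count-based test had been written first for the case that counts were deposited, and limma-trend for the case of RPKM, which applied. Comparisons within a tissue used all 9 libraries of that tissue with a mean for each group and no covariate. Differences between tissues used all 18 libraries and tested the shoot effect minus the root effect. The added 1 RPKM makes the log2 changes of genes near 1 RPKM smaller than their ratios of means, so folds given in the text are ratios of mean RPKM. Adjusted p values measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures.

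Genes were grouped by 37 lists fixed before the data were examined, as patterns matched to the protein descriptions in the tables; in 6 lists, members with unrelated proteins behind a matching word were excluded after the descriptions were seen and before any test. Usable descriptions were missing for 5707 genes. Lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 37 lists of a comparison. Members are also counted after adjustment over the list alone. Named genes follow a rule fixed at the same time. It takes called genes with a mean of at least 5 RPKM, no overlap between the libraries of the groups compared and a usable description, and of these the 6 largest rises and 6 largest falls. What counts as a usable description was narrowed after a first list of named genes had been seen, to leave out entries that give only a species name. It adds up to 8 called members of the brassinosteroid biosynthesis, inactivation and bHLH lists, and up to 3 members by smallest adjusted p of each other list called by camera, for at most 6 lists. By chance, 10% of genes have groups of 3 libraries that do not overlap.

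Opposite effects of PPZ and BL were measured as correlation and covariance across genes, beside the values from 100 random rotations without any effect, because both effects share the PPZ libraries. In addition, genes called without a given PPZ library were compared in BL against that library alone; the mock libraries took part in calling these genes. Whether replicate numbers pair libraries was checked by correlating same-numbered libraries' deviations from their group means. The library names carry an L number whose meaning is not stated in the labels; it was treated as a possible batch. It is 4, 4 and 5 in root mock, 5 in all root PPZ, 5, 8 and 2 in root BL, 5 in all shoot mock, 5, 4 and 5 in shoot PPZ and 8 in all shoot BL libraries.

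Alternatives fixed before the data were examined were no filter and a filter of 5 RPKM, a pseudocount of 0.1, other sets of libraries in the fit, the replicate number as a block, the L number as a covariate or restricted to 5, leaving out each library in turn, adjusted p under 0.01, at least a 2-fold change, and the authors' own calls. Added after seeing the data were limma-voom on the recovered reads, median-of-ratios scaling, the PPZ columns as headed in the BL tables, and the list patterns without exclusions. The pipeline was tested on simulated values with 200 changed genes per comparison. Of genes changed 2-fold it recovered 70% for root PPZ vs mock, 69% for root BL vs PPZ, 78% for root BL vs mock, 88% for shoot PPZ vs mock, 89% for shoot BL vs PPZ and 92% for shoot BL vs mock. For the tissue differences these shares were 34% in PPZ vs mock and 40% in BL vs PPZ, and between 2.2% and 7.8% of the calls were false. Of genes changed 4-fold, 94% to 100% were recovered. All changed genes were drawn from those with a mean of at least 5 RPKM, and noise was normal and independent between genes. These shares therefore do not hold for lower genes, and a comparison without calls can still hold such changes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.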

Results

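Roots and shoots of moso bamboo seedlings were compared after treatments meant to deplete the hormone brassinosteroid and then give it back. Hormone levels are not part of these data. Seedlings aged 18 days spent 5 days on medium with 10 µM propiconazole (PPZ), an inhibitor of brassinosteroid biosynthesis, or on mock medium, and some PPZ seedlings then received 1 µM brassinolide (BL), a brassinosteroid, for 4 hours. The other PPZ seedlings had a mock step of 4 hours instead, and for the mock seedlings no such step is recorded in the labels. Each tissue and treatment has 3 libraries, 18 in all, with 26584 to 28172 genes above 0 RPKM. The 10 highest genes held 5.2% to 9.1% of a library's summed RPKM. Tissue was the first principal component (63.7% of the variance), and on the second (9.9%) the root mock libraries lay between 42.1 and 49.8 and the root PPZ libraries between −35.2 and −26.1. Because the columns headed PPZ in the deposited BL tables hold the mock values, BL was compared with the PPZ columns of the other table of each tissue.

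In PPZ roots 3 of 8 measured brassinosteroid biosynthesis genes rose against mock. A cytochrome P450 gene whose nucleotide match in the tables is a CYP85A1 of Brachypodium (PH01000278G0580) rose 8.15-fold, from 5.80 ± 0.342 to 47.2 ± 5.95 RPKM (mean ± SD, n = 3; limma log2 change 2.82, adjusted p = 6.5e-05). Cytochrome P450 85A1 (PH01001995G0390), the oxidase that makes castasterone, rose 2.96-fold, from 37.5 ± 1.16 to 111 ± 7 RPKM (adjusted p = 2.5e-04). CYP724B1 (PH01000041G0270) rose 2.35-fold, from 1.77 ± 0.366 to 4.17 ± 1.24 RPKM (adjusted p = 0.0279), a call lost in 8 of 15 refits, among them no filter, L number as covariate and leaving out root mock 2, root mock 3, root PPZ 1 or root PPZ 2. Cytochrome P450 90B1 (PH01001012G0570), the DWARF4 step, had 0.773 ± 0.163 RPKM in mock and 3.58 ± 2.31 RPKM in PPZ and did not pass (adjusted p = 0.0529). The other 5 were not called, and 4 of the 8 rose adjusted over the list alone. The list passed camera (adjusted p = 0.00399), with adjusted p = 0.242 with an estimated correlation. The 6 measured genes for brassinosteroid inactivation, relatives of CYP734A, had a median log2 change of 0.01 and a smallest adjusted p of 0.0987 (camera adjusted p = 0.914).

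Of the helix-loop-helix factors of the ILI and IBH1 families, which in rice act on cell elongation under brassinosteroid control, 3 of 5 measured members fell in PPZ roots. ILI5 (PH01000519G0840) fell 23-fold, from 19.7 to 0.860 ± 0.688 RPKM (n = 3, adjusted p = 7.8e-04). An IBH1 gene (PH01000670G0490) fell from 2.06 ± 0.638 RPKM to values listed at 0. A further bHLH gene (PH01003890G0120) fell 6.69-fold to 0.476 ± 0.279 RPKM. The other 2 were not called, with 4 lower adjusted over the list alone (camera adjusted p = 8.7e-04, and adjusted p = 0.166 with an estimated correlation). Sterol biosynthesis genes, which make the precursors, fell in 5 and rose in 1 of 31 members, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0014, and adjusted p = 0.242 with an estimated correlation). Squalene synthase 1 (PH01005976G0040) fell 1.95-fold to 6.80 ± 0.681 RPKM. Sterol methyltransferase genes fell 2.03-fold (PH01000170G0230) and 1.57-fold (PH01000010G0100), calls lost in 7 and 6 of 16 refits; both were lost without root mock 3, root PPZ 2 or root PPZ 3.

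Peroxidase, cellulose synthase and Aux/IAA genes were lower as lists by camera at its preset correlation, and were not called by camera at an estimated correlation. Class III peroxidases, which act on wall polymers, fell in 23 and rose in 1 of 74 members, with 29 lower and 4 higher adjusted over the list alone (camera adjusted p = 2.4e-06, and adjusted p = 0.152 with an estimated correlation). A peroxidase (PH01002518G0180) fell 53.2-fold, from 83.7 ± 16.8 to 1.57 ± 0.413 RPKM. Members PH01000524G0300, PH01000239G0760 and PH01000977G0660 fell 8.19-fold, 11.2-fold and 5.56-fold. Cellulose synthase family genes fell in 8 and rose in 3 of 57 (camera adjusted p = 3.8e-04, and adjusted p = 0.242 with an estimated correlation). Among them, cellulose synthase A 1 (PH01000905G0290) fell 2.33-fold to 8.14 ± 0.918 RPKM, A 6 (PH01000204G0350) fell 2.20-fold to 7.71 ± 1.63 RPKM and a mixed beta glucan synthase (PH01001344G0170) fell 3.13-fold. Expansin-A17 (PH01000083G0540), a wall-loosening protein, fell from 19.4 ± 2.02 RPKM to values listed at 0 (adjusted p = 4.3e-07). The 37 measured expansins moved both ways, 5 higher and 11 lower (camera adjusted p = 0.0872). Aux/IAA repressors, early targets of auxin, fell in 10 of 28 members and rose in 0, with 14 lower and 2 higher adjusted over the list alone (limma and camera, adjusted p = 5.2e-06, and adjusted p = 0.166 with an estimated correlation). Auxin-responsive protein IAA30 (PH01001154G0590), IAA13 (PH01000554G0550) and IAA31 (PH01000105G1710) fell 3.72-fold, 3.83-fold and 4.15-fold.

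The list of defence proteins did not pass in PPZ roots, with 18 of 127 members higher and 15 lower (limma and camera, adjusted p = 0.602). Of the largest rises, a pathogenesis-related thaumatin-like protein (PH01001293G0280) rose 10.3-fold, from 39.9 ± 48.2 to 410 ± 79.1 RPKM, a primary amine oxidase (PH01000488G0570) 12.3-fold to 36 ± 4.15 RPKM and a glutathione transferase (PH01000319G0520) 13.5-fold to 27.4 ± 4.38 RPKM. Glucan endo-1,3-beta-glucosidase GII (PH01001438G0190) rose 13.6-fold and the pathogenesis-related protein PRMS (PH01000337G0770) 20.1-fold, the latter to 23.1 ± 22.6 RPKM in a call lost with no filter, with limma-voom, without root mock 3 and with L number 5 only, which leaves 1 mock library. Thiol protease SEN102 (PH01002671G0100) rose from 0.0351 ± 0.0607 to 24.0 ± 16.1 RPKM (adjusted p = 0.0452), a call lost in 10 of 16 refits and when any of the 6 libraries was left out. WRKY transcription factors rose in 17 and fell in 2 of 89, among them PH01000121G1380 (3.46-fold), PH01004514G0080 (2.40-fold) and PH01000326G0720 (6.37-fold). The WRKY list had camera adjusted p = 0.00174, and adjusted p = 0.541 with an estimated correlation. Of the largest falls, proline-rich protein DC2.15 (PH01001692G0180) went from 72.6 ± 34 RPKM to values listed at 0. Profilin-A (PH01000627G0440), which binds actin, fell 23.7-fold to 5.12 ± 2.97 RPKM. Bark storage protein A (PH01005801G0070) fell 23.5-fold and a gene described as a pre-pollination inflorescence protein (PH01000840G0550) 24.4-fold.

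Further lists passed camera in PPZ roots only with its preset correlation. Lower were pectin modification (11 lower and 4 higher of 59, adjusted p = 0.00634), glutathione S-transferases (13 and 4 of 76, adjusted p = 0.00781), aquaporins (7 and 3 of 25, adjusted p = 0.00399), ERF/DREB factors (9 and 2 of 66, adjusted p = 0.00399) and lignin biosynthesis (11 and 7 of 75, adjusted p = 0.0174). Xyloglucan-modifying XTH enzymes (5 lower and 2 higher of 24, adjusted p = 0.0362) and lipid transfer proteins (9 and 2 of 35, adjusted p = 0.0269) were also lower, and both lost the call under median-of-ratios scaling. With L number as covariate aquaporins, ERF/DREB, lignin, XTH and lipid transfer lost theirs. ABC transporters were higher (15 higher and 2 lower of 123, adjusted p = 0.00399). With an estimated correlation these lists had adjusted p = 0.152, 0.188, 0.482, 0.615, 0.696, 0.435, 0.482 and 0.403 in the order given. Histone genes had a median log2 change of −0.29 (camera adjusted p = 0.00171, and adjusted p = 0.621 with an estimated correlation), with no single member called; the smallest adjusted p of the 3 named, Histone H2A.4 (PH01000656G0670), was 0.151, at 293 ± 72.1 RPKM in mock and 192 ± 15.7 RPKM in PPZ, and the others are a histone H4 gene (PH01000653G0090) and a histone H2B.2-like gene (PH01000323G0500).

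In all, 2307 of 23476 genes differed between PPZ and mock roots (973 higher, 1334 lower, limma adjusted p), of which 1281 changed at least 2-fold (400 higher, 881 lower). With L number as covariate the count was 2072 (3837 in the same 18 libraries without it), and without root mock 3, root PPZ 2 or root PPZ 3 it was 1425, 1107 or 1309. Median-of-ratios scaling moved the split to 721 higher and 1531 lower.

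**Figure D1:**
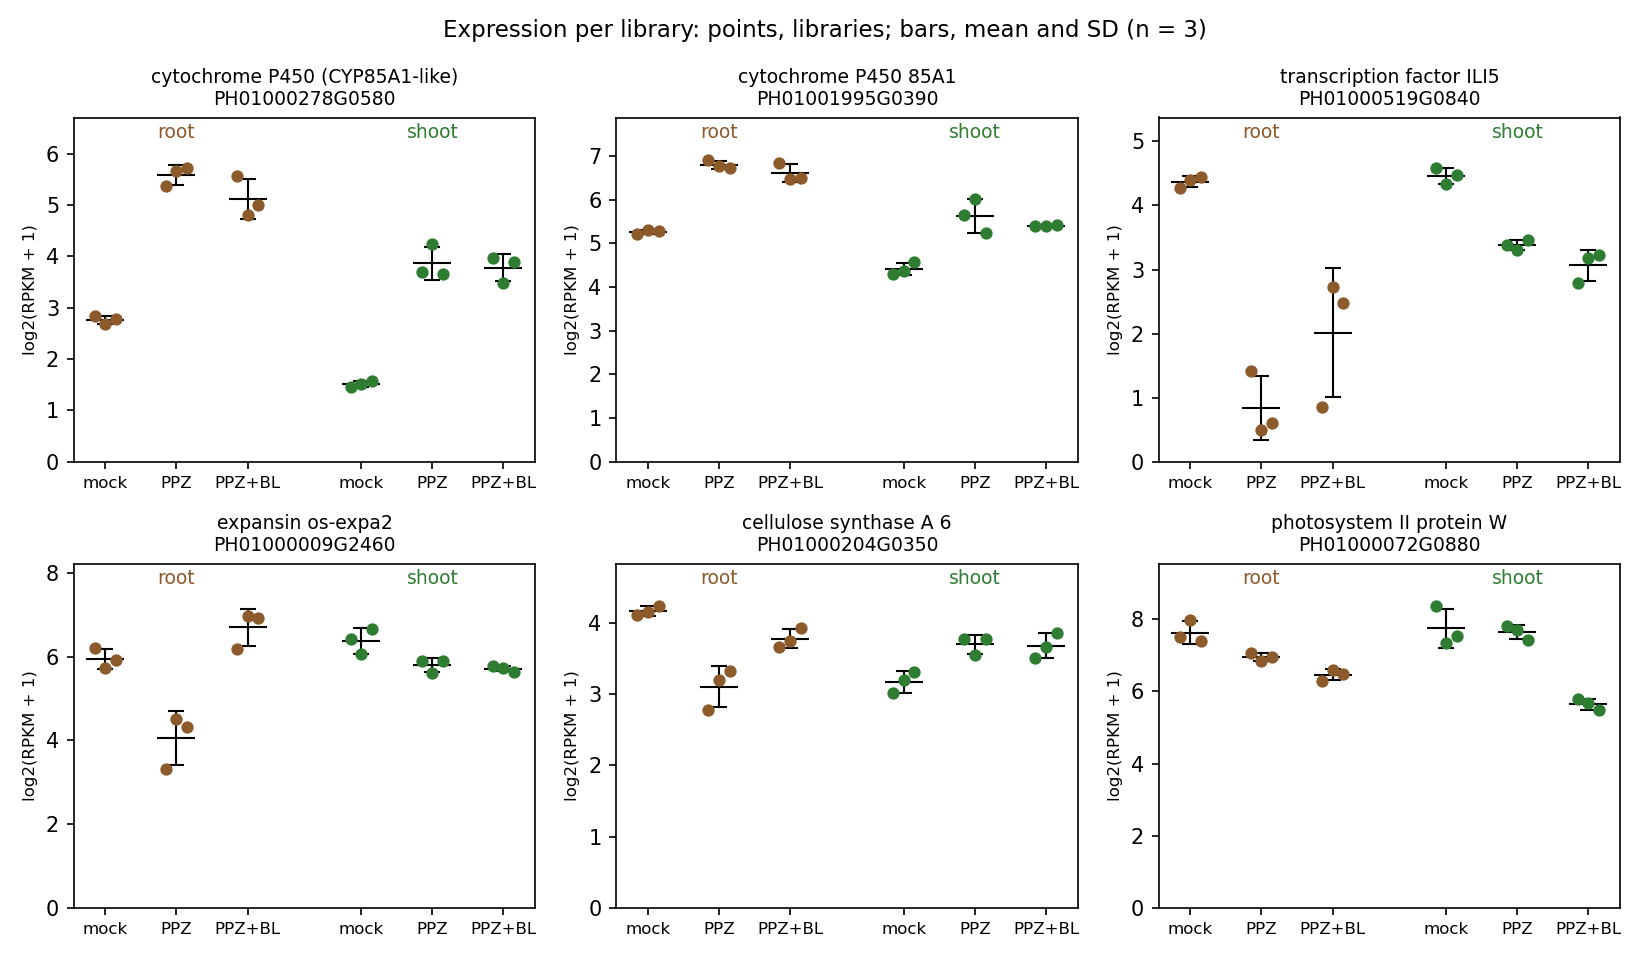
Expression of 6 named genes per library on a log2(RPKM + 1) axis, with points for libraries, bars for mean and SD (n = 3), roots in brown and shoots in green. The P450 genes are higher in PPZ than in mock in both tissues, ILI5 is lower, the expansin is low in PPZ roots, and the photosystem II gene is lowest in the shoot BL libraries.

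BL after PPZ was compared with PPZ alone in roots to ask which genes the hormone moves. Expansin genes stood higher after BL: os-expa2 (PH01000009G2460) had 16.6 ± 6.70 RPKM in PPZ and 106 ± 29.7 RPKM in BL (n = 3, 6.37-fold, limma adjusted p = 0.068). Expansin-B6-like (PH01001155G0250) had 11.3 ± 6.12 and 58.2 ± 21.6 RPKM (adjusted p = 0.217), and Expansin-A8 (PH01003538G0010) 0.216 ± 0.258 and 12.6 ± 8.36 RPKM (adjusted p = 0.217). Over all genes none of the 37 expansins was called, while 9 were higher adjusted over the list alone and 28 of 37 had a positive change (median log2 0.37). The list passed camera (adjusted p = 1.3e-09) and fry (adjusted p = 0.0299), with adjusted p = 0.0935 with an estimated correlation in camera. Mock roots had 61.0 ± 10.5, 99.3 ± 24.1 and 13.6 ± 5.99 RPKM of the same genes.

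Further lists were higher in BL than in PPZ roots by camera. Class III peroxidases had a median log2 change of 0.28 with 57 of 74 positive and 4 higher adjusted over the list alone (camera adjusted p = 4.7e-07, and adjusted p = 0.111 with an estimated correlation). Peroxidase 72 (PH01002229G0070) had 22.1 ± 10.2 and 100 ± 64.6 RPKM, a peroxidase 2-like gene (PH01002256G0210) 10.0 ± 4.54 and 37.4 ± 16.0 RPKM, and peroxidase 52 (PH01000166G0130) 87.0 ± 7.85 and 135 ± 16.6 RPKM. XTH enzymes had 21 of 24 positive and 2 higher adjusted over the list alone (median 0.32, camera adjusted p = 7.8e-05, and adjusted p = 0.164 with an estimated correlation). In this list PH01003558G0070 had 140 ± 16.7 RPKM in PPZ and 243 ± 43.0 RPKM in BL, against 434 ± 36.7 RPKM in mock. Members PH01002545G0220 and PH01002434G0010 stood 1.72-fold and 1.49-fold higher. Cellulose synthases had a median of 0.16 (camera adjusted p = 2.6e-04, and adjusted p = 0.318 with an estimated correlation), with A 6 (PH01000204G0350) at 12.8 ± 1.35 RPKM, A 1 (PH01000905G0290) at 13.4 ± 1.97 RPKM and a second A 1 gene (PH01001175G0060) at 41.8 ± 1.03 RPKM in BL. Pectin modification (median 0.15), sterol biosynthesis (0.17), bHLH factors (0.78, with 3 of 5 higher adjusted over the list alone) and reference genes such as actin and tubulin (0.12) passed camera with adjusted p = 0.0268, 0.00192, 0.00474 and 0.0133, and had adjusted p = 0.164, 0.318, 0.267 and 0.688 with an estimated correlation.

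Brassinosteroid biosynthesis genes were lower in BL than in PPZ roots as a list (median −0.30, camera adjusted p = 0.0264, and adjusted p = 0.339 with an estimated correlation), with 34.7 ± 10.1 RPKM of PH01000278G0580 and 97.2 ± 14.3 RPKM of cytochrome P450 85A1 (PH01001995G0390) in BL, both still called above mock (adjusted p = 3.5e-04 and 0.00131). Photosynthesis genes had 4 of 69 members positive and a median of −0.17 (camera adjusted p = 5.9e-09, and adjusted p = 0.339 with an estimated correlation), for example a photosystem I gene (PH01002810G0080) at 139 ± 23.4 RPKM in PPZ and 68.4 ± 3.86 RPKM in BL. Photosystem I subunit N (PH01087490G0010) stood 1.71-fold lower in BL and a plastocyanin-like domain gene (PH01000049G0360), whose family is not confined to photosynthesis, 1.62-fold higher. Histones (median −0.19) and WRKY factors (−0.14) were also lower, with camera adjusted p = 4.5e-04 and 0.00414 and both at adjusted p = 0.688 with an estimated correlation. The named histones, PH01001339G0120, PH01001117G0440 and PH01000359G0640, stood 1.26-fold, 1.44-fold and 1.31-fold lower in BL. With L number as covariate 7 of the 12 list calls of this comparison were lost: XTH, sterol biosynthesis, bHLH, reference genes, brassinosteroid biosynthesis, photosynthesis and WRKY. With fry 10 of 12 were lost.

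No gene passed limma-trend over all 23476 genes in this comparison: 0 were called, the smallest adjusted p was 0.0509, and 1509 genes had an unadjusted p under 0.05 where 1174 are expected by chance. Limma-voom on recovered reads called 1, the fit of all 18 libraries 18, and the fit without root BL 1 called 13. Among these, os-expa2 (PH01000009G2460) passed with limma-voom, with all 18 libraries and without root BL 1. Expansin-A8 (PH01003538G0010) passed in the last 2 of these fits and Expansin-B6-like (PH01001155G0250) with all 18 libraries. With L number as covariate the root BL mean rests on root BL 1 alone, so that fit does not test these calls.

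PPZ and BL effects in roots were opposite across genes (Spearman −0.47, Pearson −0.54 over 23476 genes, which are not independent replicates). Rotations without any effect gave a mean Spearman of −0.46 (SD 0.26), since both effects share the PPZ libraries, so the correlation alone says little. The covariance was −0.0845 against a mean of −0.033 (SD 0.0238, range −0.114 to 0.00953) in 100 rotations, so it lay within their range. When genes were chosen without a given PPZ library and BL was set against that library alone, genes lowered by PPZ stood higher in BL by a median log2 of 0.24, 0.38 and 0.35 for the 3 libraries, where mock stood higher by 1.22, 1.40 and 1.33. The mock libraries took part in choosing the genes, which inflates the mock medians, so the share of the way back to mock is not measured. Of these genes 69.8%, 85.3% and 82.4% were higher in BL, against 50.2%, 53.1% and 49.5% of all genes. Genes raised by PPZ stood lower in BL by medians of −0.18, −0.38 and −0.24, with 71.3%, 84.6% and 74.0% lower. All 3 root PPZ libraries have L number 5, as do 1 of 3 mock and 1 of 3 BL libraries. A shift that goes with the L number could move mock and BL the same way, and leaving out a PPZ library does not remove it.

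**Figure D2:**
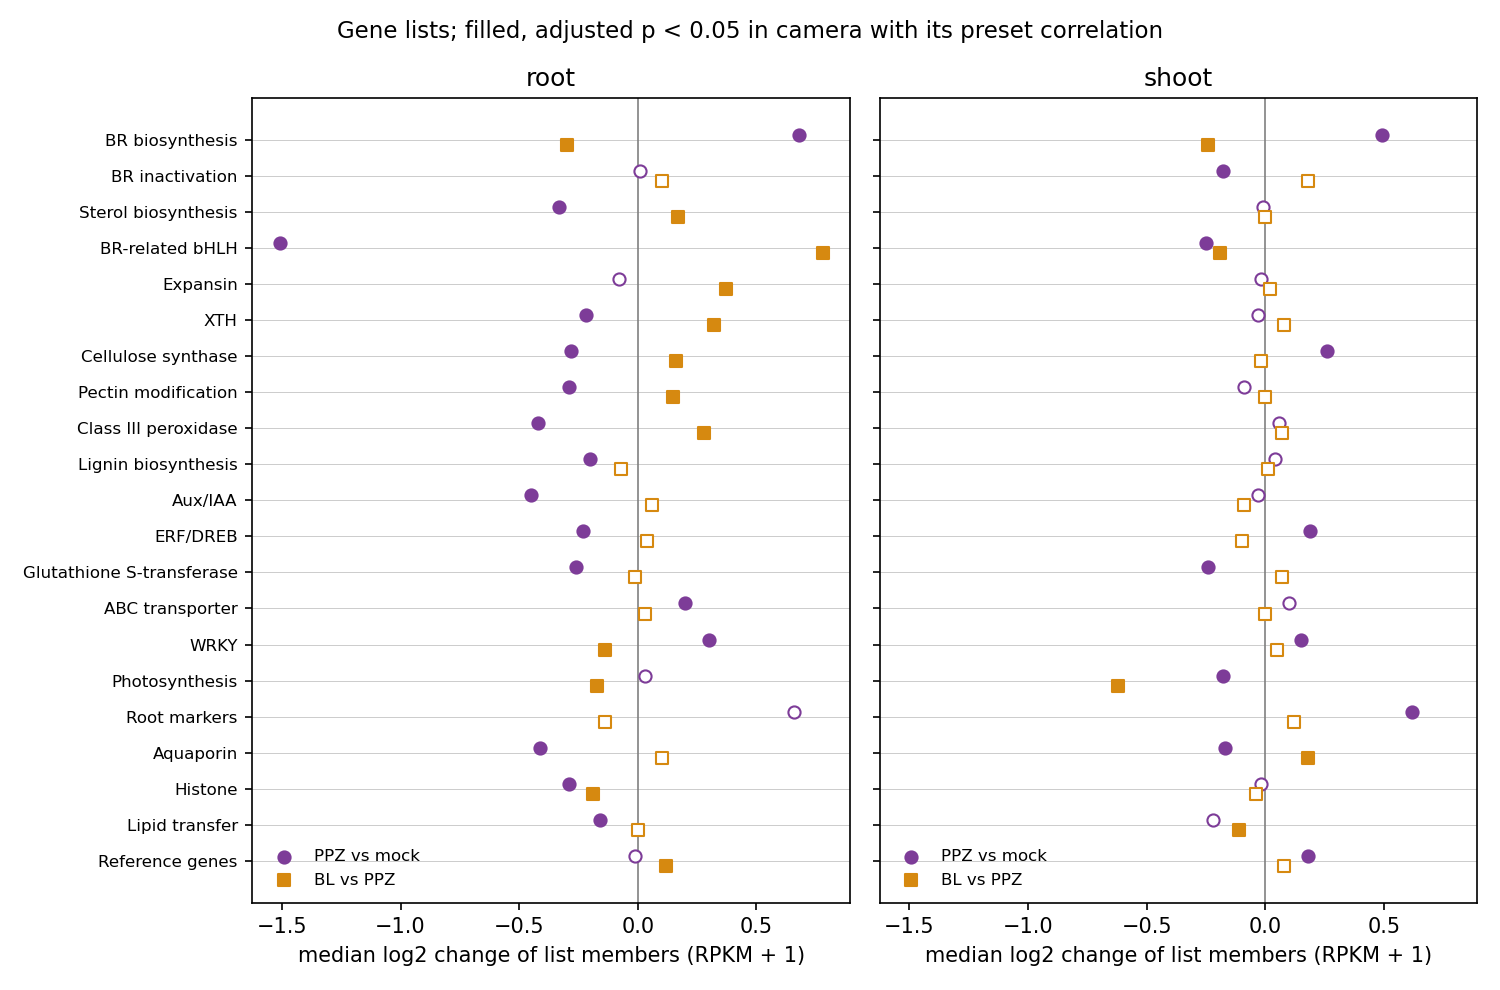
Median log2 change, on log2(RPKM + 1), of the members of the gene lists in roots (left) and shoots (right), for PPZ vs mock (circles) and BL vs PPZ (squares), filled where camera with its preset correlation gave adjusted p under 0.05. In roots the expansin, XTH, cellulose synthase, pectin and peroxidase lists lie below 0 in PPZ and above 0 in BL, in shoots the photosynthesis list lies lowest in BL at −0.62, and no list keeps its call with an estimated correlation.

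In shoots 3 of 8 measured biosynthesis genes rose as well. In PPZ shoots PH01000278G0580 rose 7.40-fold, from 1.87 ± 0.120 to 13.8 ± 3.55 RPKM (n = 3, limma adjusted p = 0.00148). CYP724B1 (PH01000041G0270) rose 2.94-fold to 7.58 ± 1.45 RPKM (adjusted p = 0.0126) and cytochrome P450 85A1 (PH01001995G0390) 2.44-fold to 49.9 ± 13.5 RPKM (adjusted p = 0.0134). The other 5 were not called, with 4 higher adjusted over the list alone (camera adjusted p = 9.4e-06, and adjusted p = 0.091 with an estimated correlation). ILI5 (PH01000519G0840) fell 2.23-fold, from 21.1 ± 1.90 to 9.45 ± 0.569 RPKM. A gene that matches ILI4-like (PH01000065G2010) fell 3.99-fold to 2.94 ± 1.02 RPKM. These were 2 of 9 measured bHLH members, with 4 lower adjusted over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.419 with an estimated correlation). Inactivation genes had a median of −0.18, with 1 of 7 lower adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.333 with an estimated correlation).

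Cellulose synthase family genes rose in PPZ shoots, in 5 of 67 members with 0 lower, or 18 higher and 3 lower adjusted over the list alone (limma and camera, adjusted p = 7.4e-04, and adjusted p = 0.419 with an estimated correlation). Cellulose synthase A 1 (PH01001175G0060) rose 1.91-fold to 57.3 ± 4.97 RPKM, A 8 (PH01001427G0390) 1.78-fold to 35.4 ± 3.37 RPKM and a xyloglucan glycosyltransferase (PH01000379G0160) 1.88-fold. WRKY factors rose in 3 of 105 members (13 higher and 2 lower adjusted over the list alone): WRKY 50 (PH01004940G0100) 2.33-fold, WRKY 41-like (PH01000046G1680) 2.67-fold and WRKY 33-like (PH01002744G0230) 3.25-fold. ERF/DREB factors rose in 4 and fell in 1 of 75, with PH01007432G0010 up 2.04-fold and PH01000171G0880 up 6.31-fold, while the AP2-like factor ANT (PH01003525G0030) had 6.37 ± 0.396 and 10.7 ± 2 RPKM (adjusted p = 0.0646). Camera gave these lists adjusted p = 0.0233 and 0.0274, and both had adjusted p = 0.691 with an estimated correlation. The list written as root markers (1 higher and 1 lower of 9, median 0.62), of which 4 members are higher in shoot mock than in root mock, and reference genes (median 0.18, 4 higher of 52 adjusted over the list alone) passed camera with adjusted p = 0.0284 and 0.0369, and had adjusted p = 0.383 and 0.691 with an estimated correlation; both calls ended with the list patterns as first written.

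In PPZ shoots 3 of 80 glutathione S-transferases and 4 of 26 aquaporins fell, and neither list passed camera with an estimated correlation. A glutathione S-transferase (PH01167425G0010) fell 6.24-fold, from 116 ± 34.5 to 18.6 ± 8.76 RPKM. Members PH01001049G0620 and PH01003493G0040 fell 2.36-fold and 2.91-fold. The list had 3 lower and 2 higher of 80, or 15 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.9e-06, and adjusted p = 0.162 with an estimated correlation). Aquaporins, which carry water or small solutes, fell in 4 of 26 members (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.4e-04, and adjusted p = 0.549 with an estimated correlation). Aquaporin NIP2-1 (PH01000135G1100) fell 4.76-fold to 2.22 ± 0.585 RPKM, a PIP aquaporin (PH01000001G4670) 3.42-fold to 11.6 ± 0.599 RPKM and PIP2-2 (PH01003141G0240) 3.42-fold. Photosynthesis genes had a median of −0.18 without a called member (smallest adjusted p 0.104; camera adjusted p = 9.4e-06, and adjusted p = 0.691 with an estimated correlation); the named members PH01001161G0430, PH01000331G0860 and PH01000656G0610 stood 1.46-fold, 1.55-fold and 1.81-fold lower.

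Among the largest changes, ornithine decarboxylase (PH01000703G0260), the enzyme that makes putrescine, fell 6.87-fold, from 97.8 ± 46.3 to 14.2 ± 5.42 RPKM. An O-methyltransferase (PH01002583G0060) fell 4.06-fold, a jasmonate-induced protein (PH01003146G0030) 5.01-fold and a gene described as loricrin (PH01001051G0040) 3.95-fold. Phenylalanine ammonia-lyase (PH01006951G0050), the entry to phenylpropanoids, rose 6.03-fold to 21.8 ± 8.83 RPKM and an aromatic-L-amino-acid decarboxylase (PH01003589G0180) 6.41-fold to 20.3 ± 13.2 RPKM. A calcium-binding EF-hand gene (PH01000411G0840), phi-1 (PH01000943G0050) and a C2H2 zinc finger gene (PH01001743G0130) rose 10.9-fold, 7.45-fold and 6.14-fold.

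In PPZ shoots 480 of 24641 genes differed from mock (297 higher, 183 lower), 196 of them at least 2-fold. The count was 15 in libraries of L number 5 (3 mock and 2 PPZ) and 185 with L number as covariate (431 in the same libraries without it), 31, 181, 797, 164 and 16 without shoot mock 1, shoot mock 2, shoot PPZ 1, shoot PPZ 2 and shoot PPZ 3, and 301 (154 higher, 147 lower) under median-of-ratios scaling. Of the 28 called genes named for this comparison 26 lost their call in at least 1 of 16 refits, and PH01000278G0580 and PH01000001G4670 never did.

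Photosynthesis genes were lower in BL than in PPZ shoots as a list by camera at its preset correlation only. A photosystem II reaction center W gene (PH01000072G0880) fell 4.06-fold, from 200 ± 27.9 to 49.3 ± 5.16 RPKM (n = 3, limma adjusted p = 0.0308). Calvin cycle protein CP12-1 (PH01000578G0270) fell 2.74-fold, from 693 ± 72.9 to 253 ± 30 RPKM (adjusted p = 0.0308). NAD(P)H-quinone oxidoreductase subunit T (PH01000315G0180) fell 2.55-fold and the ribosomal protein L34 gene (PH01001028G0140) 2.64-fold. Of 71 photosynthesis members 1 fell over all genes and 55 fell adjusted over the list alone, with 2 of 71 positive and a median log2 change of −0.62. Camera gave the list adjusted p = 4.7e-38, and adjusted p = 0.354 with an estimated correlation. The photosystem II 23kDa polypeptide (PH01000331G0860) had 290 ± 32.9 RPKM in PPZ and 138 ± 22 RPKM in BL (adjusted p = 0.0718), and a member whose descriptions name both a photosystem I antenna protein and a succinyl-CoA ligase (PH01001895G0420) stood 2.46-fold lower. All BL shoot libraries have L number 8, which no mock or PPZ library has, so batch and BL cannot be told apart within shoots. The list's median was −0.61 with L number as covariate over all 18 libraries, with a median SE of 0.4 in place of 0.2. That fit takes the L number 8 effect from 1 root library, so it does not separate batch from BL.

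The same glutathione S-transferase that PPZ had lowered (PH01167425G0010) rose 3.65-fold after BL, to 67.9 ± 11.1 RPKM. Aquaporin PIP1-5 (PH01000788G0340) rose 2.53-fold, from 44.3 ± 14.9 to 112 ± 14.2 RPKM. A chitinase (PH01000384G0030), an NBS-LRR disease resistance gene (PH01001967G0220), alcohol dehydrogenase 3 (PH01007610G0010) and a gene described as isoflavone expressed (PH01000260G0330) rose 2.25-fold, 2.20-fold, 2.12-fold and 1.79-fold. Aquaporins as a list had 20 of 26 positive and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00465, and adjusted p = 0.847 with an estimated correlation), with PH01000001G4670 at 19.7 ± 3.28 RPKM and PIP2-7 (PH01000332G0830) 3.90-fold lower at adjusted p = 0.164. A DIR1-like lipid transfer protein (PH01002296G0200) fell 3.11-fold to 46.4 ± 11.4 RPKM, 1 of 36 lipid transfer members over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0251, and adjusted p = 0.847 with an estimated correlation). In that list PH01001053G0160 and PH01000012G1020 stood 3.14-fold and 2.61-fold lower. Bem46 (PH01001650G0300) fell 3.83-fold. Brassinosteroid biosynthesis genes (median −0.24, 0 of 8 positive) and bHLH factors (median −0.19) passed camera with adjusted p = 0.036 each, and had adjusted p = 0.354 and 0.571 with an estimated correlation.

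In this comparison 38 of 24641 genes were called (9 higher, 29 lower), 31 of them at least 2-fold. Each of the 12 called genes named here lost its call in 8 to 11 of 15 refits. With L number as covariate (94 in the same 18 libraries without it) or under median-of-ratios scaling limma called 0 (2529 and 2465 genes at an unadjusted p under 0.05, and 40 by limma-voom in the fit without covariate), and without any single library it called 0 except for 6 without shoot PPZ 3.

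Effects of PPZ and BL in shoots were not opposite across genes (Spearman 0.04, Pearson 0.02, covariance 0.00168, over 24641 genes). All shoot BL libraries have L number 8, which no shoot mock or PPZ library has. A batch shift would thus be part of the BL effect measured in this paragraph and cannot be told apart from it. Rotations without any effect gave a mean Spearman of −0.46 (SD 0.21, range −0.89 to 0.17). Their mean covariance was −0.0244 (SD 0.0126, range −0.061 to 0.005). The shoot Spearman and covariance lay within these ranges, so they are not told apart from no effect. Of the 297 genes that rose in PPZ and the 29 that fell in BL, 0 were shared where independent lists would share 0.35. Of the 183 genes that fell in PPZ and the 9 that rose in BL, 5 were shared where independent lists would share 0.0668, and these calls share the PPZ libraries. They are the glutathione S-transferase (PH01167425G0010), aquaporin PIP1-5 (PH01000788G0340) and PH01000260G0330, and, named after their values were seen, a pyruvate dehydrogenase subunit gene (PH01001262G0280; 2.94 ± 0.394, 1.32 ± 0.334 and 4.20 ± 0.720 RPKM in mock, PPZ and BL) and a lipase class 3-like gene (PH01001512G0170; 3.32 ± 1.01, 0.203 ± 0.138 and 4.03 ± 2.56 RPKM). Set against a PPZ library left out of their choice, the 275, 76 and 9 genes lowered by PPZ had medians of −0.31, −0.08 and 0.27 in BL, with 22.9%, 38.2% and 66.7% higher, against 40%, 55.5% and 54.3% of all genes, and mock, which took part in the choice, stood higher by 0.46, 0.81 and 1.52. The 522, 88 and 7 genes raised by PPZ had 0.41, 0.12 and 0.13, with 13.2%, 35.2% and 28.6% lower, and medians of −0.52, −0.93 and −1.27 in mock.

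Seedlings given BL after PPZ differed from mock. In roots 1056 of 23476 genes did (372 higher, 684 lower): Aux/IAA repressors were lower in 9 of 28 members (13 adjusted over the list alone, camera adjusted p = 1.4e-06, and adjusted p = 0.222 with an estimated correlation), while expansins were higher in 10 and lower in 3 of 37 (camera adjusted p = 0.255). ILI5 (PH01000519G0840) was at 3.66 ± 2.52 RPKM after BL, 5.39-fold below mock (adjusted p = 0.0135), and, named after its values were seen, an IBH1 gene (PH01000026G0110) at 5.40 ± 0.874 RPKM, 3-fold above it (adjusted p = 0.028). In shoots 3261 of 24641 genes differed (1620 higher, 1641 lower), and 50 of 71 photosynthesis genes were lower (60 adjusted over the list alone, median −0.86, camera adjusted p = 3.9e-28, and adjusted p = 0.575 with an estimated correlation). Shoot ILI5 (PH01000519G0840) was 2.84-fold below mock at 7.44 ± 1.31 RPKM, 1 of 4 lower bHLH members among 9 (camera adjusted p = 0.00102, and adjusted p = 0.575 with an estimated correlation). The root count was 577, 612 and 446 without root mock 3, root BL 2 and root BL 3. It split 259 higher and 803 lower under median-of-ratios scaling. The shoot count was 15 with L number as covariate (2860 in the same libraries without it) and 1125, 1872, 1533 and 1565 without shoot mock 1 and shoot BL 1, 2 and 3. All shoot BL libraries have L number 8 and all shoot mock libraries 5, so batch and treatment cannot be told apart in this shoot comparison. The covariate takes its L number 8 effect from 1 root library, so the shoot count with it does not show a batch effect. In roots it leaves the BL mean to root BL 1 alone, so it does not test batch there.

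**Figure D3:**
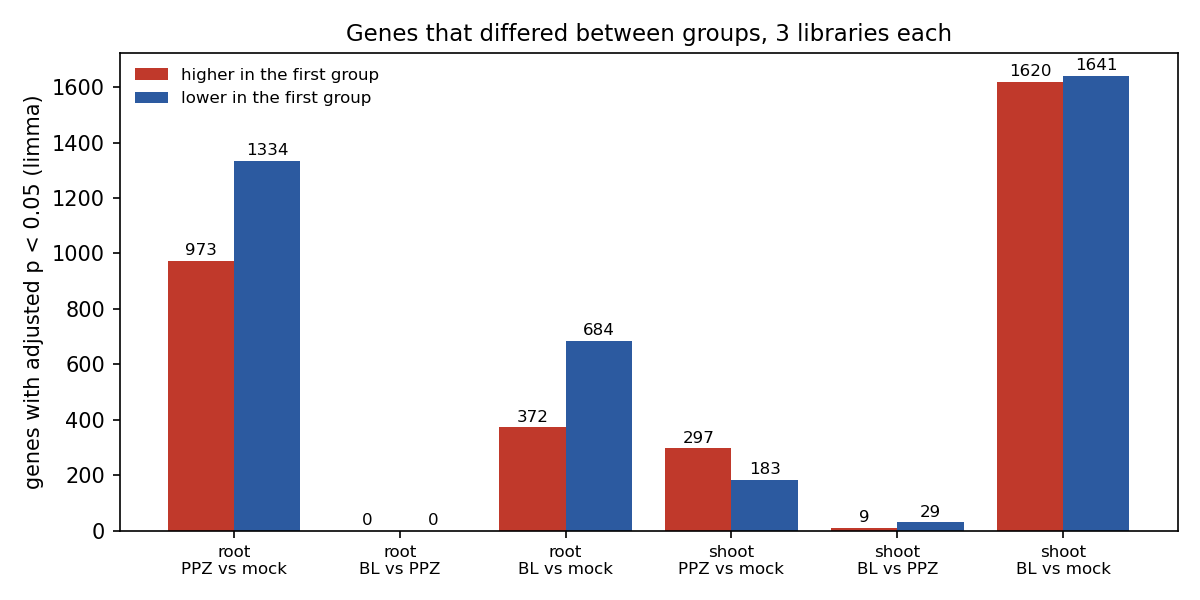
Number of genes called by limma (adjusted p under 0.05) in each comparison of groups of 3 libraries within a tissue, higher (red) and lower (blue) in the first group named. The counts range from 0 for BL vs PPZ in roots to 1641 lower genes for BL vs mock in shoots.

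The effect of PPZ differed between shoot and root in 1318 of 25384 genes (950 with a higher, 368 with a lower change in shoots). Cellulose synthases had a median difference of 0.43 on the log2 scale (camera adjusted p = 3.2e-08, and adjusted p = 0.226 with an estimated correlation), with A 1 (PH01000905G0290) at 1.77 and A 6 (PH01000204G0350) at 1.59. Class III peroxidases (median 0.51) and Aux/IAA repressors (0.31) also differed (camera adjusted p = 3.2e-06 and 5.4e-04, and both at adjusted p = 0.268 with an estimated correlation). Expansin-A17 (PH01000083G0540) differed by 4.35 (adjusted p = 6.8e-11), but it was listed at 0 in all shoot libraries, so this restates its fall in roots. For the biosynthesis genes PH01000278G0580 and PH01001995G0390 the difference was −0.48 ± 0.28 and −0.32 ± 0.23 (SE), adjusted p = 0.386 and 0.49. The effect of BL differed in 3 genes, with all 3 lower in shoots: os-expa2 (PH01000009G2460) by −2.73 and, named after their values were seen, a UDP-glycosyltransferase 73C5 gene (PH01001707G0440) by −1.52 and a STAMENLESS 1-like zinc finger gene (PH01000663G0100) by −1.24, each at adjusted p = 0.0295. These calls are not stable, with 0 genes under the block and 0 when any of root PPZ 3, root BL 2, root BL 3, shoot PPZ 1, shoot PPZ 2 or a shoot BL library was left out. The zinc finger gene (PH01000663G0100) was listed at 0 in mock and PPZ roots and was not tested there, so its difference rests on the shoot change from 9.16 ± 1.46 to 3.45 ± 0.315 RPKM. UGT73C5 glucosylates brassinosteroids in Arabidopsis, and the bamboo gene had 5.63 ± 1.09, 0.383 ± 0.0982 and 2.34 ± 0.620 RPKM in mock, PPZ and BL roots. With L number as covariate the PPZ count was 685. Without shoot PPZ 3 the PPZ count was 848, and without root BL 1 the BL count was 27.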

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

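For the photosynthesis pattern and the heading conflict, the tests on depth, on green tissue and on the headings were chosen only after the results they measure were seen. The other tests were written after the patterns and the counts of calls were known, but before the values they measure were seen. Values below are shoot minus root differences in log2 change, from limma on all 18 libraries, and what singles these results out is a difference between the tissues.

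These genes had a lower change with PPZ in roots than in shoots. The difference was 6.17 for DC2.15 (PH01001692G0180), 4.72 for a peroxidase (PH01002518G0180), 4.32 for profilin-A (PH01000627G0440), 5.43 for bark storage protein A (PH01005801G0070), 5.45 for PH01000840G0550 and 4.35 for Expansin-A17 (PH01000083G0540). Of these, DC2.15 (PH01001692G0180), PH01000840G0550 and Expansin-A17 (PH01000083G0540) were at 0 RPKM in shoot mock and not tested in shoots, so for them the difference restates the root fall. The peroxidase (PH01002518G0180) had 25 and 19.9 RPKM in shoot mock and shoot PPZ, profilin-A (PH01000627G0440) 20.1 and 19.5 RPKM and bark storage protein A (PH01005801G0070) 4.95 and 10.5 RPKM. Peroxidases PH01000524G0300, PH01000239G0760 and PH01000977G0660 differed by 2.87, 3.10 and 1.72, where PH01000239G0760 had only 0.0186 RPKM in shoot mock and was not tested in shoots either. Aux/IAA genes PH01001154G0590, PH01000554G0550 and PH01000105G1710 differed by 1.92, 1.70 and 2.16. ILI5 (PH01000519G0840) differed by 2.46, IBH1 (PH01000670G0490) by 1.34 and PH01003890G0120 by 1.71. Squalene synthase 1 (PH01005976G0040) differed by 0.86 and a sterol methyltransferase (PH01000170G0230) by 1.18.

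Cellulose synthase family genes had 8 lower and 3 higher members in PPZ roots and 5 higher in PPZ shoots. PH01000905G0290, PH01000204G0350 and PH01001344G0170 differed by 1.77, 1.59 and 1.99, and PH01001175G0060, PH01001427G0390 and PH01000379G0160 by 1.37, 1.05 and 0.97. The EF-hand gene (PH01000411G0840) differed by 2.51 and GSTF10 (PH01003493G0040) by 2.08. Genes with the lower change in shoots were the thaumatin-like protein (PH01001293G0280, −3.57), a glutathione transferase (PH01000319G0520, −2.74), glucanase GII (PH01001438G0190, −2.28), primary amine oxidase (PH01000488G0570, −3.68), WRKY factors PH01004514G0080 (−0.87) and PH01000326G0720 (−1.98), aquaporin NIP2-1 (PH01000135G1100, −1.79) and PH01000065G2010 (−1.50), which had 0.357 RPKM in root mock and was not tested in roots.

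As lists, the PPZ effect differed by medians of 0.43 for cellulose synthase, 0.51 for peroxidases, 0.31 for Aux/IAA, 0.49 for ERF/DREB, 0.25 for sterol biosynthesis, 0.29 for XTH, 0.22 for lignin biosynthesis, 0.26 for reference genes and −0.22 for photosynthesis. Camera gave these adjusted p = 3.2e-08, 3.2e-06, 5.4e-04, 3.9e-04, 0.00643, 0.0257, 0.00915, 0.00629 and 0.0475. With an estimated correlation the adjusted p were 0.226, 0.268, 0.268, 0.663, 0.623, 0.663, 0.742, 0.663 and 0.936. The BL effect differed by −0.39 for expansins, −0.56 for bHLH factors, −0.26 for sterol biosynthesis, −0.20 for cellulose synthase, −0.23 for peroxidases, −0.47 for photosynthesis, 0.14 for WRKY and 0.13 for histones. Camera gave adjusted p = 1.1e-05, 2.5e-04, 0.00666, 0.0044, 0.00666, 1.9e-13, 0.0044 and 0.0469, and 0.241, 0.241, 0.541, 0.541, 0.548, 0.541, 0.651 and 0.871 with an estimated correlation.

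Over all genes 1318 differed in the PPZ effect, and 6 of 100 random splits, the real one included, called as many, with at most 1662 in another split, so chance is not excluded for the count. For the BL effect 3 genes differed, led by os-expa2 (PH01000009G2460) at −2.73, and 12 of 100 splits called as many, with at most 75, so chance is not excluded here either. Random splits can keep the real grouping of 1 tissue. Within a tissue only 10 splits exist, so their share cannot go below 0.1 and chance cannot be excluded by them. The real grouping called 2307, 1056, 480 and 3261 genes in root PPZ vs mock, root BL vs mock, shoot PPZ vs mock and shoot BL vs mock, where the highest other split called 0 and the real one alone reached its count (1 of 10 in each). Shoot BL vs PPZ had 38 against 12 in the highest other split (1 of 10), and root BL vs PPZ had 0 in all 10.

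The lower photosynthesis genes in BL shoots (median −0.62) might come from library batch, from depth, from less green tissue or from BL. The BL shoots share L number 8 with 1 root library. That library deviated from its group with a Spearman of −0.07 to the shoot change across 3019 genes. The 49 photosynthesis members among these genes deviated in it by a median log2 of 0.06. The covariate left the median of the list at −0.61 with a median SE of 0.40 in place of 0.20. These values rest on 1 root library, so batch stays open. Low read numbers do not account for the fall of the 47 members with at least 100 RPKM, which had a median of −0.65. All of them were lower (100%), but nearly all members of the whole list were lower, so that share tests nothing further. Of the 9 members of the root marker list 4 are higher in shoot mock than in root mock, so the list does not separate the tissues and its median of 0.12 tests nothing. Less green tissue stays open, as no other test of it was made. Median RPKM of the members was 152, 138 and 175 in the BL libraries, 239, 271 and 239 in PPZ and 353, 195 and 253 in mock.

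The columns headed PPZ in the BL tables hold mock values, and an error in their headings is 1 possible reason. Mock and PPZ headings exchanged in the PPZ tables could be another, and biosynthesis genes should then be lower in the columns headed PPZ. However, 6 of 6 called changes were higher, which argues against it. These are the same genes in both tissues (PH01000278G0580, PH01001995G0390 and PH01000041G0270), not 6 separate checks. The BL table headings could also be right and the values those of PPZ. The columns headed mock in the PPZ tables would then hold PPZ values, as under an exchange, so these explanations are not separate. The same genes should then fall from those columns to BL, but 5 of 5 called changes were higher. Both tests rest on the same genes and assume that loss of brassinosteroid raises them and BL lowers them. Their rise in PPZ is therefore not separate evidence for the headings.

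No gene was called between BL and PPZ roots, which may reflect wider spread in the BL roots, a single deviating library, or an effect within the noise. The spread of the BL libraries was 1.22 times that of the PPZ libraries, between the limits set beforehand, so that test decides nothing. Spread in the BL roots does not set this comparison apart from the other root comparisons, since all of them use the same pooled SE for a gene, and the mock libraries had a wider median SD (0.254 in root mock, 0.202 in root BL) with 2307 and 1056 genes called against mock. Whether less spread would have given calls stays open. Leaving out 1 library gave at most 13 calls, without root BL 1, which is under the limit set. Each such fit also loses a library, so few calls cannot exclude a deviating library. Without root BL 1, 2015 genes had an unadjusted p under 0.05, against 986 to 1354 without any other PPZ or BL library. The chi-square per gene of root BL 1 was 30.4 and 21.1 against root BL 2 and 3, which had 9.4 between them. A deviating root BL 1 stays open. For an effect within the noise, 2 of 10 splits, the real one included, had as many genes at an unadjusted p under 0.05, which meets its prediction. The real one had 1509 and the highest other 1831. That other split sets root PPZ 1, root PPZ 2 and root BL 1 against the rest. It keeps most libraries in their real groups and exchanges root BL 1 and root PPZ 3, so it does not measure noise alone. The test does not tell noise from a deviating root BL 1.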

How the results depend on the processing

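Median-of-ratios scaling, limma-voom, the headed PPZ columns and the first list patterns were tests chosen only after the results were seen; all other alternatives were chosen before the data were examined. DESeq2 and its size factors were not run, as the unit is RPKM. Libraries of L number 5 alone could not be compared for the shoot BL comparisons, for the tissue difference of BL or for shoot opposition. In roots they are 1 mock, 3 PPZ and 1 BL library, so their root values rest on arms of 1 library and show little. With L number as covariate the root BL mean likewise rests on root BL 1 alone, so values of that fit that involve BL roots show little. No call of a named gene reversed its direction under the refits of its own groups, and no called list was called in the opposite direction. Whether a list that lost its call changed direction was not counted. The cause of the changes below was not tested. The columns as headed, which set BL against mock, gave the opposite direction for 8 of 18 named genes and 9 of 12 called lists of root BL vs PPZ and 2 of 18 named genes and 2 of 5 called lists of shoot BL vs PPZ.

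Root PPZ vs mock (2307 genes) gave 3837 with all 18 libraries in the fit, 1465 with L number 5 only, 940 at adjusted p under 0.01, 1281 with at least 2-fold, and 1107 to 2407 leaving out 1 library (1425 without root mock 3, 1107 without root PPZ 2, 1309 without root PPZ 3). Root BL vs PPZ (0) gave 1 without filter, 1 with the stricter filter, 18 with all 18 libraries, 5 with L number as covariate, 2 with pseudocount 0.1, 1 with limma-voom and 0 to 13 leaving out 1 library (13 without root BL 1). The authors' calls under that heading number 1687, read here as against mock, and the columns as headed give 1056, against mock values. Root BL vs mock (1056) gave 499 without filter, 692 with 6 libraries, 2200 with all 18, 625 with the block, 623 with the covariate, 207 with L number 5 only, 271 at adjusted p under 0.01, 676 with at least 2-fold, and 446 to 992 leaving out 1 library (577 without root mock 3, 612 without root BL 2, 446 without root BL 3).

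Shoot PPZ vs mock (480) gave 12 without filter, 169 with 6 libraries, 185 with the covariate, 15 with L number 5 only, 301 with median-of-ratios scaling, 9 at adjusted p under 0.01, 196 with at least 2-fold and 980 by the authors' calls. Leaving out 1 library gave 16 to 797 (31 without shoot mock 1, 181 without shoot mock 2, 797 without shoot PPZ 1, 164 without shoot PPZ 2, 16 without shoot PPZ 3). Shoot BL vs PPZ (38) gave 5 without filter, 143 with 6 libraries, 94 with all 18, 60 with the block, 0 with the covariate, 0 with median-of-ratios scaling and 0 at adjusted p under 0.01. The authors' calls number 4306, read here as against mock, and the columns as headed give 3261, against mock values. Leaving out 1 library gave 0 to 6 (6 without shoot PPZ 3, 0 without each other library). Shoot BL vs mock (3261) gave 1838 without filter, 15 with the covariate, 787 at adjusted p under 0.01, 796 with at least 2-fold and 1125 to 3044 leaving out 1 library (1125 without shoot mock 1, 1872, 1533 and 1565 without shoot BL 1, 2 and 3).

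The tissue difference in PPZ vs mock (1318) gave 685 with the covariate, 789 with L number 5 only, 506 at adjusted p under 0.01 and 848 to 1588 leaving out 1 library (848 without shoot PPZ 3). The tissue difference in BL vs PPZ (3) gave 1 without filter, 1 with the stricter filter, 0 with the block, 19 with the covariate, 1 with limma-voom, 0 at adjusted p under 0.01 and 0 to 27 leaving out 1 library (27 without root BL 1, 1 without root PPZ 1, root PPZ 2 or shoot PPZ 3, and 0 without each other library). The Spearman of PPZ and BL effects stayed within −0.55 to −0.39 in roots leaving out 1 library, with −0.30 with the covariate and −0.33 with L number 5 only. In shoots it was −0.13 with the covariate and 0.12 with the stricter filter.

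The covariate was fitted to all 18 libraries, so its counts are set beside those of 18 libraries without it. They were 2072 beside 3837 in root PPZ vs mock and 185 beside 431 in shoot PPZ vs mock. For BL they were 0 beside 94 in shoot BL vs PPZ and 15 beside 2860 in shoot BL vs mock. In these shoot BL comparisons the L number effect comes from 1 root library, so the lower counts do not show a batch effect. Counts that involve BL roots are not set side by side, because their BL mean rests on root BL 1 alone. How much of any drop goes with batch was not tested.

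Of the called genes named in root PPZ vs mock 26 of 33 kept the call in all refits (other filters, libraries, covariate, block, pseudocount, scaling and limma-voom), 28 at adjusted p under 0.01, 29 with at least 2-fold and 25 in all of these. Those lost in a refit are PH01002671G0100 (lost in 10 of 16), PH01000041G0270 (8 of 15), PH01000170G0230 (7), PH01000010G0100 (6), PH01000337G0770 (4), PH01001293G0280 (1, no filter) and PH01000204G0350 (1, L number 5 only). In shoot PPZ vs mock 2 of 28 kept it in all refits, 4 at adjusted p under 0.01 and 24 with at least 2-fold. In shoot BL vs PPZ 0, 0 and 11 of 12 did, with 8 to 11 of 15 refits lost for each gene.

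With an estimated correlation in camera 0 lists were called in any comparison, against 16, 12 and 12 in root PPZ vs mock, root BL vs PPZ and root BL vs mock and 11, 5 and 6 in the shoot comparisons. With fry 2 lists were called in root BL vs PPZ, 6 in shoot PPZ vs mock and 0 in shoot BL vs PPZ. Besides these, L number as covariate lost 5 of 16 list calls in root PPZ vs mock (aquaporin, ERF/DREB, lignin, lipid transfer and XTH), 7 of 12 in root BL vs PPZ, 5 of 12 in root BL vs mock, 1 of 11 in shoot PPZ vs mock, 2 of 5 in shoot BL vs PPZ and 3 of 6 in shoot BL vs mock. Leaving out root mock 2 lost 6 of 16 in root PPZ vs mock. With fry 5 of 16, 10 of 12, 6 of 12, 7 of 11, 5 of 5 and 4 of 6 were lost in the same order. Same-numbered libraries had residual correlations of −0.39 to 0.05 in roots and −0.18 to 0.05 in shoots. In each tissue 0 of 9 were over 0.1, so no strong shared effect of replicate number was seen. The block moved no other count of calls over 1.5 times. The labels do not say whether replicate numbers pair libraries, and these values do not settle it. Recovered depth limits genes under 1 RPKM, where 1 read in 1000 bp is 0.039 to 0.065 RPKM.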

Other observations

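Groups of genes that share a word in their descriptions were tested only after the results were seen, with camera over 897 words in roots and 933 in shoots, and adjusted p values below are over these words. None of these groups keeps its call with an estimated correlation. Blue copper proteins and copper transporters were lower in PPZ roots in 13 and higher in 3 of 37 members (median log2 −0.60, adjusted p = 7.6e-04, and adjusted p = 0.935 with an estimated correlation). Arabinogalactan proteins, components of the wall and plasma membrane surface, were lower in 9 of 22 (median −0.78, adjusted p = 2.3e-05), and germin-like proteins in 5 of 13 (median −0.84, adjusted p = 0.00772). Amyloplastic proteins, such as starch synthases, were higher in 9 of 20 (median 0.84, adjusted p = 2.5e-04). With an estimated correlation the adjusted p of the last 3 groups was 0.988 each.

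TIFY proteins, which include the jasmonate ZIM repressors, were higher in 5 of 15 members in PPZ shoots (median 0.62, camera adjusted p = 4.4e-05, not called with an estimated correlation), and ammonia-lyases in 3 of 10 (median 0.66, adjusted p = 0.00145, not called with an estimated correlation). In BL against PPZ shoots NAD(P)H-quinone oxidoreductase genes were lower in 2 of 9 (median −0.86, adjusted p = 1.0e-09, adjusted p = 0.997 with an estimated correlation) and constans-like genes had a median of −0.38 without a called member (adjusted p = 0.00148, adjusted p = 0.997 with an estimated correlation). Metallothionein-like genes had a median of −0.61 in BL against PPZ roots without a called member (adjusted p = 0.00423, adjusted p = 0.996 with an estimated correlation).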
